A study of Mus musculus with 14 samples.

How the data were processed

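Total RNA of sorted cells from C57BL/6 mice was labelled with a low-input amplification kit and hybridised to single-colour Agilent arrays, per the labels' protocols. The 14 arrays form 7 groups of 2. By their labels, GMP lack lineage markers, IL-7R, Sca-1 and CD115 and carry CD117 and Fc gamma receptors. CDP lack lineage markers, IL-7R and Sca-1, have intermediate CD117 and carry CD115 and CD135. Pre-cDC lack lineage markers and MHC class II and carry CD11c, CD135 and CD172a. Both kinds of cDC carry CD11c and MHC class II with either CD4 or CD8, and neutrophils carry CD11b and high Ly6G. Genes that encode these markers (Csf1r, Kit, Flt3, Itgax, the class II genes, Cd4, Cd8a, Sirpa, Itgam, Ly6g and the Fc receptor genes) are no findings between groups whose gates differ in them. The CD4+ cDC were purified with magnetic beads alone and the neutrophils by flow cytometry alone; the others had both.

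The scanner values are spot intensities that Agilent Feature Extraction 10.7.3.1 made from the images, per the file headers: the processed signal is background-subtracted and detrended within each array, with small positive values in place of signals not above background, and it is not normalized between arrays. The table deposited by the authors holds intensities of the same arrays on a linear scale for 39429 probes; how it was made is not given in the sources used here. Its sorted values were the same in all 14 columns (median 46.02), as after quantile normalization, and for probes with a single spot each column followed the order of its array's processed signal (Spearman correlation 0.999999), so its scale and direction were settled by this comparison. Of the arrays, 12 are of a larger design and the CD4+ cDC arrays of a smaller one, whose 39429 probes the larger design also holds.

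Control spots and spots marked as outliers by the scanner software were left out, which left 59305 spots of 55681 probes on the larger design and 43020 spots on the smaller. The log2 of the processed signal was averaged over the spots of a probe, and each array's 75th percentile was subtracted. A probe was well above background on an array where at least a share of 0.5 of its spots were so marked by the scanner software. Probes were named through their accession in the RefSeq table of assembly GRCm38.p6, used for names alone; 26762 probes had 1 symbol, which gave 20284 genes, and 28919 had none, of which 16194 are named in the files by a genomic interval. A gene with several probes took its brightest. No spot was saturated, and no column of values was left unmapped. What limits these data is the signal over background, given with the results, and the number of arrays.

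Each of 6 comparisons was fitted with limma 3.58.1 (lmFit, contrasts and eBayes, two-sided) in R 4.3.3 with the package data.table (1.17.8), on the 12 arrays of the larger design together, which share 1 estimate of the spread per gene (prior degrees of freedom 1.56, total 7.56). Figures were drawn with Python 3.11.15 and matplotlib 3.10.9. Benjamini-Hochberg adjustment ran over the genes well above background on both arrays of at least 1 of the groups compared, and a gene was called at an adjusted p under 0.05. Errors given as SE come from this fit, and SD is between the 2 arrays of a group. At-least folds are for genes not well above background on any array of the dimmer group: the brighter group's mean is set against the mean, over the dimmer group's arrays, of the higher of the array's lowest signal among probes well above background and the probe's own. The same bounds replace the fitted changes in the list medians given at bounds, which stand beside a called list where they move its median by over 0.1. The design, the gene lists and the rule for naming genes were set before the data were examined.

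The 23 gene lists are cDC1 programme, cDC2 programme, dendritic cell core, MHC class II presentation, plasmacytoid dendritic cell markers, monocyte and macrophage, primary granule, secondary and tertiary granule with mature neutrophil, basophil and mast cell, eosinophil, erythroid and megakaryocyte, stem and progenitor, B lymphoid, T and NK lymphoid, cell cycle, ribosome biogenesis and MYC targets, interferon response, Toll-like receptors and adaptors, chemokine receptors, haematopoietic transcription factors, stress and dissociation, cytokine and growth factor receptors, and reference genes. Each was tested against all other genes with camera of limma, two-sided, with a preset correlation of 0.01 and adjusted over the lists of a comparison, and again with an estimated correlation. Where a median is followed by p-values in brackets, these are camera's adjusted p. A list's direction in camera is relative to the other genes, so it can differ in sign from the list's own median. Counts of list members are calls over all genes tested; outside the comparison of the arrays labelled IRF8KO, the counts adjusted over the list alone differed from these by at most 1 gene for every list. Genes at least 2-fold lower or higher in the arrays labelled IRF8KO GMP were tested by camera as 2 further sets in the 5 other comparisons, adjusted over these 10 tests. In the comparisons that share WT GMP they were tested again among genes that passed the filter of both comparisons (for the lower set, well above background on both WT GMP arrays), adjusted over 4 tests. Their medians were set beside 100 draws of genes outside the sets, matched in 10 classes of the WT GMP level. This control was added after the data were seen. Controls shared between comparisons were simulated 100 times with unchanged groups.

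The genes that could be named were, among calls of at least 2-fold whose groups did not overlap, the largest changes measured on every array (8 in each direction for the arrays labelled IRF8KO GMP and 5 for the others), the largest at-least folds (3 and 2 in each direction), up to 4 members of each list with the largest change, Irf8 throughout, and 4 genes for each pair of directions with the largest product of changes for the overlap. The text names part of them. The code was tested on simulated data for the comparison of the arrays labelled IRF8KO GMP with WT GMP, over 12141 genes: it recovered 61.2% of 67 genes changed 1.5-fold, 82.1% of 67 changed 2-fold and 100% of 66 changed 4-fold, and 3.57% of 168 calls were false.

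The arrays lay on 5 slides. Both GMP groups shared one, CD8+ cDC and neutrophils another, and CDP, pre-cDC and CD4+ cDC each had their own, so a within-slide value exists for a pair of comparisons and is the fit of only the 4 arrays compared. That fit leaves each change as it was and alters only the estimate of its spread. The alternatives were normexp background correction (offset 50) on the median spot signal, as the files hold no mean spot signal, quantile normalization, array medians, the authors' table, no filter or a stricter filter on dim probes, the mean or the median-change probe of a gene, only the 4 arrays compared, the replicate number as a block, a trended and robust variance, at least 2-fold, an adjusted p under 0.01, an estimated correlation, and each array left out in turn. The percentile over probes well above background on all 12 arrays was added after the data were seen. The CD4+ cDC arrays entered no test, because their design, slide and group cannot be told apart.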

Results

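Gene expression was measured in purified mouse blood cell populations on 14 single-colour oligonucleotide arrays, 2 for each of 7 groups. Granulocyte-monocyte progenitors (GMP) came from the bone marrow of wild-type (WT) mice and of mice labelled IRF8KO. IRF8 is a transcription factor of the interferon regulatory factor family. The other groups came from wild-type mice: common dendritic cell progenitors (CDP), precursors of classical dendritic cells (pre-cDC) and neutrophils (Neu) from bone marrow, and CD8+ and CD4+ classical dendritic cells (cDC) from spleen. Ly6C+ monocytes, which the series title names, were not analysed here.

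Signal strength differed between the groups. The 75th percentile of the processed signal was 508 to 584 on the 4 GMP arrays, 88.8 and 89.4 on the CDP arrays, 182 and 164 on the pre-cDC arrays, 236 and 316 on the CD8+ cDC arrays, 163 and 148 on the Neu arrays, and 706 and 607 on the CD4+ cDC arrays. On the 12 arrays of the larger design, 40.2% to 54.2% of probes were well above background, and no spot was saturated. The CD4+ cDC arrays were of a smaller design, on which 62.0% and 60.3% of probes were well above background, so this group entered no test. Within a group, the replicate arrays correlated across genes at r = 0.996 to 0.998, and the median gene differed by 0.0598 (WT GMP) to 0.102 (CD8+ cDC) on the log2 scale. Across 13559 genes, the first principal component held 53.5% of the variance and set the Neu arrays apart, and the second, with 25.9%, ran from the GMP arrays to the CD8+ cDC arrays. The number of arrays limits the precision of every value. The labels do not say whether replicates came from separate animals, so the p-values measure only the spread between these samples, which may be technical.

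The targeted gene was read first, as a check of the labels. The probe for Irf8 (gene 15900) was brighter on the arrays labelled IRF8KO GMP, at 6.19 ± 0.04 (SD, n = 2) on the log2 scale relative to the array's 75th percentile, than in WT GMP, at 4.83 ± 0.05 (SD, n = 2). The difference was 1.36 ± 0.07 (SE), with limma's adjusted p = 1.39e-05, and within the slide that held both groups, from those 4 arrays alone, adjusted p = 0.00256. The array carries 1 probe for Irf8, whose position in the gene is not in the sources used here, so it cannot check the deletion. Directions below therefore compare the arrays labelled IRF8KO with the arrays labelled WT. In the wild-type cells the probe read 8.97 in CDP, 9.08 in pre-cDC, 8.62 in CD8+ cDC and 0.03 in Neu. It rose from GMP to CDP by 4.14 ± 0.07 (SE, adjusted p = 6.25e-09) and fell by 4.80 ± 0.07 (SE, adjusted p = 2.77e-10) from GMP to Neu.

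**Figure D1:**
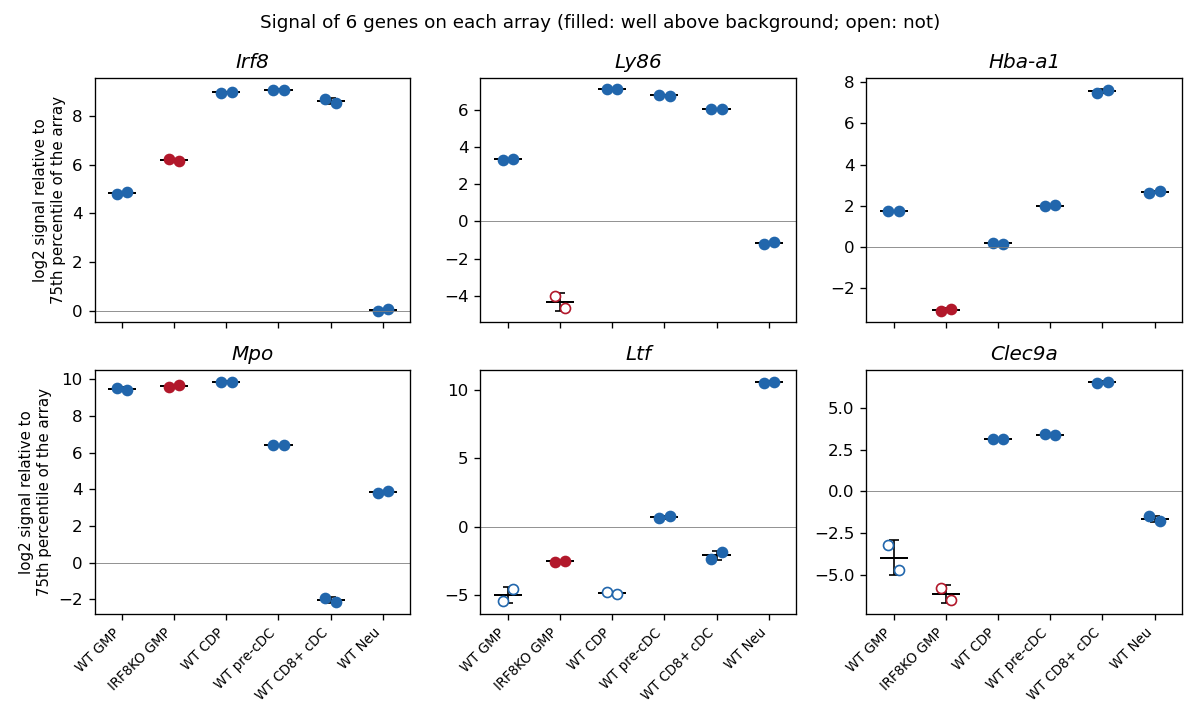
Signal of Irf8, Ly86, Hba-a1, Mpo, Ltf and Clec9a on each array of 6 groups, on the log2 scale relative to the array's 75th percentile; points are arrays (open where not well above background), bars the mean and SD of the 2 arrays of a group. Irf8 is brighter on the arrays labelled IRF8KO GMP (6.19) than on the WT GMP arrays (4.83), and Ly86 is well above background on every array shown except those labelled IRF8KO GMP.

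The comparison of the arrays labelled IRF8KO GMP with WT GMP asks which transcripts of this progenitor gate depend on the genotype. Genes of red cells, basophils and eosinophils fell together. Of 12 measured members of the erythroid and megakaryocyte list, 11 fell and none rose (median -2.28 on the log2 scale). The alpha globin gene Hba-a1 changed by -4.78 ± 0.06 (SE, n = 2 arrays per group throughout) and the carbonic anhydrase gene Car1 by -4.41 ± 0.07. The erythroid transcription factor gene Klf1 changed by -3.87 ± 0.53, and Epor, which encodes the erythropoietin receptor, by -3.33 ± 0.09. All 12 basophil and mast cell genes fell (median -1.77, and -1.63 at bounds, that is, with members not well above background in the dimmer group at their bound). Among them were Fcer1a and Ms4a2, which encode chains of the high-affinity IgE receptor (-4.09 ± 0.17 and -2.85 ± 0.15), and Il1rl1, the gene of the interleukin receptor ST2 (-2.78 ± 0.15). Of 6 eosinophil genes, 4 fell (median -1.46), including those for the granule proteins Prg2 (-1.77 ± 0.09) and Epx (-1.78 ± 0.22). By camera over the 23 gene lists, the adjusted p was 6.32e-12 for the erythroid, 3.95e-11 for the basophil and 0.00185 for the eosinophil list. The first and second held with an estimated correlation (0.00576 and 0.00875), and the eosinophil list had adjusted p = 0.0748 with an estimated correlation. Adjusted over the list alone, 11, 12 and 4 members fell.

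Neutrophil granule genes rose in the arrays labelled IRF8KO GMP. Of 16 measured genes of secondary and tertiary granules and mature neutrophils, 11 rose and none fell (median 1.54, and 1.01 at bounds, camera adjusted p = 6.26e-07, and 0.0109 with an estimated correlation, 13 rose adjusted over the list alone). The chitinase-like gene Chil3 rose by 2.61 ± 0.30 (SE). The neutrophil surface glycoprotein gene Cd177 was at least 3.75-fold higher and the lactoferrin gene Ltf at least 2.10-fold higher, both not well above background in WT GMP. The collagenase gene Mmp8 rose by 5.04 ± 0.70, with 1 of the 2 WT arrays well above background. Of 13 primary granule genes, 8 rose and none fell (median 0.601, adjusted p = 6.69e-05, and 0.0215 with an estimated correlation, 9 adjusted over the list alone), with the ficolin gene Fcnb at 1.39 ± 0.19 and the granulocytic transcription factor gene Gfi1 at 1.03 ± 0.19.

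Monocyte and antigen presentation genes split. In the monocyte and macrophage list 12 of 15 rose and 2 fell (median 1.08, adjusted p = 0.000147, adjusted p = 0.0748 with an estimated correlation, 12 and 3 adjusted over the list alone). The chemokine receptor gene Ccr2 rose by 2.41 ± 0.20 (SE), the macrophage receptor gene Adgre1 by 2.10 ± 0.06, and the coagulation factor gene F13a1 by 1.90 ± 0.26. Against these, Ly86, which encodes the partner of a Toll-like receptor relative on B cells and macrophages, read 3.36 in WT GMP and was not well above background in the arrays labelled IRF8KO, at least 169-fold lower (adjusted p = 4.75e-07). Among 12 MHC class II genes 6 fell and 1 rose (median -0.381, adjusted p = 0.000785, adjusted p = 0.0748 with an estimated correlation, 7 and 2 adjusted over the list alone). The invariant chain gene Cd74 changed by -2.81 ± 0.13, the class II beta chain gene H2-Eb1 by -2.42 ± 0.11, and H2-Aa was at least 2.41-fold lower.

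The core, cDC1 and cDC2 lists were not called in the arrays labelled IRF8KO GMP. In the core list 4 of 12 members rose and 3 fell (median -0.117, mean 0.382, adjusted p = 0.893), with Itgax, the CD11c gene, higher by 2.32 ± 0.07 (SE). In the cDC1 list 2 of 7 rose and 1 fell (median -0.059, mean 0.152, adjusted p = 0.828), and in the cDC2 list 1 of 10 rose and 1 fell (median 0.114, mean -0.00172, adjusted p = 0.718); in these 3 lists the median and the mean differ in sign. Of 10 plasmacytoid dendritic cell genes, 4 rose (median 0.185, adjusted p = 0.0363, adjusted p = 0.225 with an estimated correlation), led by Cox6a2, a subunit gene of cytochrome c oxidase, at 3.16 ± 0.05. Of 4 B lymphoid genes 3 rose (median 1.03, adjusted p = 0.0105, adjusted p = 0.0748 with an estimated correlation), with the surrogate light chain gene Vpreb1 at 1.69 ± 0.23. Dntt, the terminal transferase gene of early lymphoid cells, rose by 3.13 ± 0.07, outside the lists. Of 4 T and NK genes 1 rose and 1 fell (median -1.10, adjusted p = 0.293).

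Among genes of immature cells, 6 of 16 stem and progenitor genes fell and 2 rose in the arrays labelled IRF8KO (median -0.234, adjusted p = 0.0177, adjusted p = 0.0752 with an estimated correlation). The transcription factor genes Gata2, Mycn and Meis1 changed by -2.20 ± 0.22 (SE), -1.54 ± 0.22 and -1.07 ± 0.07. Of 25 cell cycle genes 12 fell and none rose, by small amounts (median -0.267, adjusted p = 1.03e-07, adjusted p = 0.158 with an estimated correlation, 15 adjusted over the list alone): Ccna2, the cyclin A2 gene, changed by -0.48 ± 0.06, a call lost with array medians (adjusted p = 0.0930). In the ribosome biogenesis and MYC target list 4 of 16 fell (median -0.151, adjusted p = 0.0137, adjusted p = 0.172 with an estimated correlation). Cytokine receptor genes mostly rose, 12 of 19 against 2 that fell (median 0.350, adjusted p = 0.00197, adjusted p = 0.165 with an estimated correlation, 13 and 3 adjusted over the list alone). The M-CSF receptor gene Csf1r rose by 1.11 ± 0.05, and it encodes CD115, whose absence was part of the gate of both groups.

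Of 16 Toll-like receptor and adaptor genes 9 rose and none fell in the arrays labelled IRF8KO (median 0.388, adjusted p = 0.000721, and 0.0341 with an estimated correlation, 12 adjusted over the list alone), with Unc93b1, the chaperone gene of nucleic acid-sensing receptors, at 0.96 ± 0.05 (SE). Of 5 chemokine receptor genes 3 rose (median 0.301, adjusted p = 0.0448, adjusted p = 0.142 with an estimated correlation). The remaining lists were not called: interferon response (5 rose and 3 fell of 13, median 0.315, adjusted p = 0.377), and haematopoietic transcription factors (13 and 6 of 30, median 0.122, adjusted p = 0.284). Nor were stress and dissociation (4 and 0 of 11, median 0.194, adjusted p = 0.0687, the immediate early gene Fos by 2.46 ± 0.06) and reference genes (2 and 0 of 10, median 0.0368, adjusted p = 0.893). The stress list passed without WT GMP replicate 2 (0.0389), without IRF8KO GMP replicate 1 (0.0225), with array medians (0.0360) and with no filter on dim probes (0.00603). With no filter the interferon and transcription factor lists passed too (0.0413 and 0.0280), the latter with its median on the other side of 0 (-0.0150). Among single genes outside the lists, Sphk1, a sphingosine kinase gene, changed by -5.12 ± 0.16, and Tmem178, a transmembrane protein gene, was at least 45.3-fold higher.

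Of 12141 genes tested between the arrays labelled IRF8KO GMP and WT GMP, 3050 passed, 1837 higher and 1213 lower. The share of higher calls was 60.2%, and it depended on the scaling: 51.9% with quantile normalization, 53.1% in the authors' table, 50.7% with the percentile over probes detected on all arrays, 58.6% with normexp and 65.4% with array medians. At least 2-fold changes numbered 628, of which 300 were higher and 328 lower. Of the 23 lists 15 passed, and 5 with an estimated correlation. The fit of only these 4 arrays, which share a slide, called 3729 genes and 13 lists. There, the plasmacytoid and chemokine receptor lists were not called (adjusted p = 0.0663 and 0.0696). The plasmacytoid list also lost its call without IRF8KO GMP replicate 2 (adjusted p = 0.126), and the chemokine receptor list without that array (0.0732) or WT GMP replicate 2 (0.0987). With no filter on dim probes, the stem (0.131), ribosome (0.127), B lymphoid (0.274) and chemokine receptor lists (0.164) were not called. Some medians moved by over 1.5 times: the secondary granule list to 0.909 with normexp, the ribosome list to -0.0802 with array medians, and the stem list to -0.396 without WT GMP replicate 1 and -0.121 without WT GMP replicate 2. With no filter on dim probes the medians were -0.213 (class II), 0.104 (plasmacytoid), 0.0679 (B lymphoid) and 0.0506 (chemokine receptors). The count of genes rested on both arrays of each group: it was 1869 without WT GMP replicate 1, 1762 without WT GMP replicate 2, 1662 without IRF8KO GMP replicate 1 and 1821 without IRF8KO GMP replicate 2, and it was 1484 with each array scaled to its median.

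**Figure D2:**
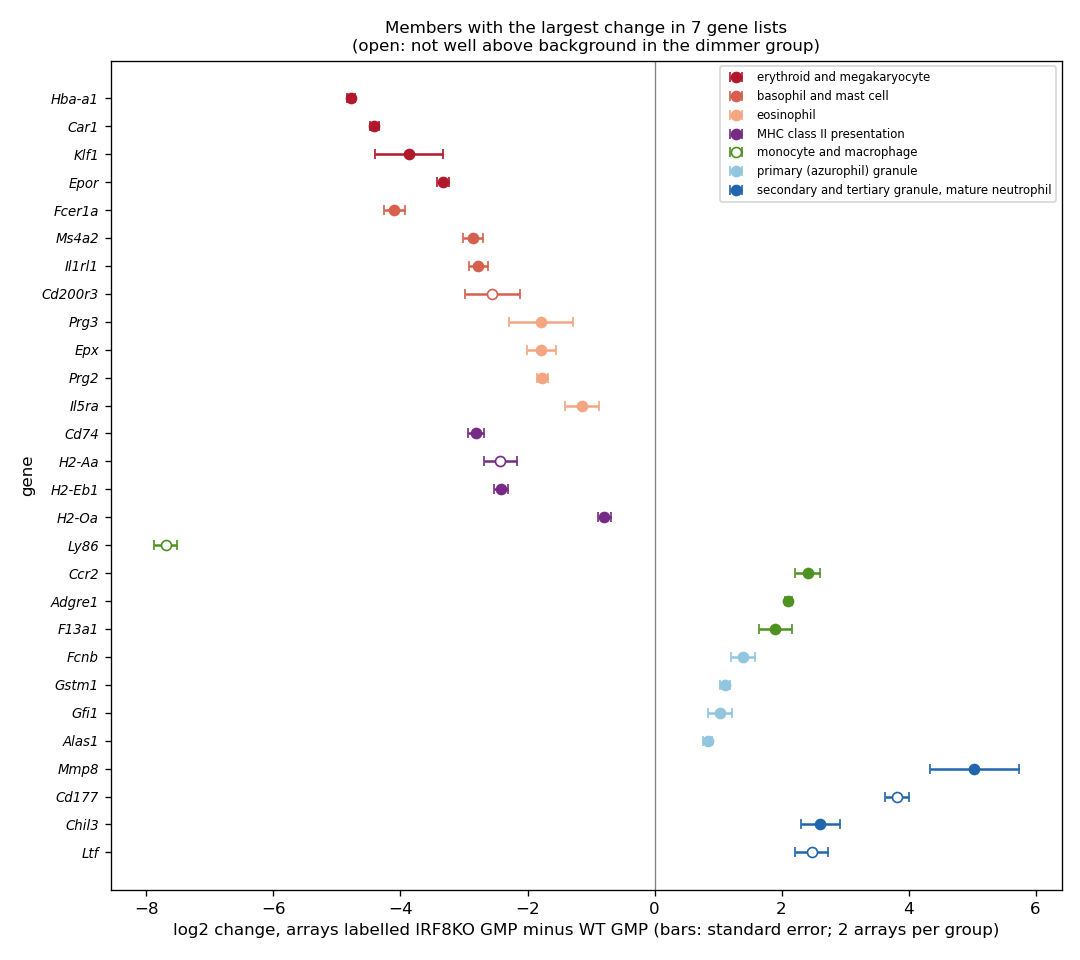
Log2 change of the 28 members named from 7 gene lists, arrays labelled IRF8KO GMP minus WT GMP; points are fitted changes (open where the dimmer group was not well above background), bars the standard error, with 2 arrays per group. Erythroid, basophil and eosinophil genes lie below 0, and primary and secondary granule genes above 0.

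The step from WT GMP to WT CDP asks what separates the dendritic cell progenitor from the granulocyte-monocyte progenitor. Monocyte and dendritic cell genes were higher in CDP. Of 16 monocyte and macrophage genes 14 rose (median 3.71, adjusted p = 0.000845, adjusted p = 0.110 with an estimated correlation): the transcription factor gene Klf4 by 6.20 ± 0.08 (SE), the fractalkine receptor gene Cx3cr1 by 4.85 ± 0.07, and the fibronectin gene Fn1 by at least 124-fold. Of 14 dendritic cell core genes 13 rose (median 2.60, adjusted p = 0.00126, adjusted p = 0.153 with an estimated correlation), including Kmo, a kynurenine pathway enzyme gene, by 4.53 ± 0.07. Of 11 MHC class II genes 9 rose (median 1.52, adjusted p = 0.0393, adjusted p = 0.157 with an estimated correlation). Among them were the cathepsin gene Ctss (4.51 ± 0.06) and the lysosomal thiol reductase gene Ifi30 (4.45 ± 0.06). Lgmn, also on this list and given below, rose by more than either. Of 9 measured cDC1 genes 7 rose, among them the transcription factor gene Batf3, at least 5.57-fold higher, and Clec9a, a receptor gene for dead cells, which read 3.15 in CDP and was not well above background in GMP. The list missed the threshold (median 1.95, adjusted p = 0.0585) and passed without WT GMP replicate 1 (0.0384), WT GMP replicate 2 (0.0407) or CDP replicate 1 (0.0495). It also passed with normexp (0.0356), quantile normalization (0.0405), array medians (0.0227), the authors' table (0.0366) and the percentile over detected probes (0.0239).

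Granulocyte, basophil and red cell genes were lower in CDP than in GMP. Of 13 primary granule genes 12 fell (median -2.60, and -2.11 at bounds, adjusted p = 4.48e-07, and 0.0124 with an estimated correlation), among them Elane, the neutrophil elastase gene, by 5.01 ± 0.05 (SE). Secondary granule genes fell in 8 of 11 cases (median -2.17, and -1.59 at bounds, adjusted p = 0.00122, and 0.0494 with an estimated correlation), with the alarmin gene S100a8 at least 53.6-fold lower, but the list's median was -0.661 with normexp and -0.0495 with no filter on dim probes. Basophil genes fell in 12 of 12 cases (median -4.13, and -3.52 at bounds, adjusted p = 3.98e-08, and 0.0124 with an estimated correlation). Eosinophil genes fell in 6 of 6 (median -4.07, adjusted p = 7.92e-05, and 0.0494) and erythroid genes in 11 of 12 (median -4.09, and -3.82 at bounds, adjusted p = 1.18e-06, and 0.0124). Gata2, Gata1, the eosinophil granule gene Prg2 and Car1 changed by -5.53 ± 0.22, -4.37 ± 0.18, -5.00 ± 0.09 and -6.22 ± 0.07, and the granulocyte transcription factor gene Cebpe by -6.48 ± 0.16. Kit, which encodes the gate marker CD117, changed by -3.01 ± 0.06 and Csf1r (CD115) by 3.94 ± 0.05; both defined the gates and are no findings.

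Cell cycle genes rose in CDP in 21 of 25 cases (median 1.18, adjusted p = 0.00920, adjusted p = 0.427 with an estimated correlation), with Birc5, the survivin gene, at 2.15 ± 0.05 (SE). Ribosome biogenesis genes fell in 9 of 16 (median -0.476, adjusted p = 0.00540, adjusted p = 0.157 with an estimated correlation) and stem and progenitor genes in 9 of 16 (median -0.860, and -0.526 at bounds, adjusted p = 0.0162, adjusted p = 0.110 with an estimated correlation). The reference genes rose in 10 of 10 (median 0.798, adjusted p = 0.0161, adjusted p = 0.157 with an estimated correlation), but their median was -0.267 with quantile normalization, -0.235 in the authors' table and 0.146 with normexp, none of these called. The calcium-binding protein gene S100a4 (7.94 ± 0.08) and Lgmn, a lysosomal protease gene (7.66 ± 0.19), had the largest rises among genes measured on all 4 arrays. The median of the T and NK genes was above 0 and their mean below it (0.782 and -0.431, adjusted p = 0.901). Of 11884 genes tested, 9272 passed (66.5% higher), 4120 of them at least 2-fold, and 12 lists passed, 5 with an estimated correlation. The median change of all tested genes was 0.310 and moved to 0.119 with normexp, 0.0135 with quantile normalization, 0.0239 in the authors' table and -0.203 with the percentile taken over probes detected on all arrays. The share of calls that were higher was 51.7%, 52.4% and 40.4% under the last 3 of these. The class II list lost its call with a stricter filter on dim probes (adjusted p = 0.0668) and the stem list with the percentile over detected probes (0.0898). Medians moved by over 1.5 times for the cell cycle list (0.512 with quantile normalization to 0.664 with the percentile over detected probes) and the ribosome list (-0.991 with quantile normalization to -0.816 with normexp). The stem list had medians of -0.162 with a stricter filter and -1.37 with the percentile over detected probes, which also gave 1.01 for class II. With that percentile the reference genes had a median of 0.285. Lists not called here passed under other settings: plasmacytoid with the percentile over detected probes (0.0415), stress with normexp (0.0143), and transcription factors with normexp (0.0403), quantile normalization (0.0172), the authors' table (0.0203) and the percentile over detected probes (0.00583). Each group lay on its own slide, so slide and cell type cannot be told apart in this comparison.

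From WT CDP to WT pre-cDC, the step toward committed dendritic cell precursors, plasmacytoid dendritic cell genes rose. Of 14 plasmacytoid dendritic cell genes 13 rose and none fell (median 1.98, adjusted p = 2.69e-09, and 0.0282 with an estimated correlation): the chemokine receptor gene Ccr9 by at least 45.8-fold, the transcription factor gene Spib by 4.45 ± 0.27 (SE) and Ly6d, a surface protein gene, by 4.12 ± 0.26. Among MHC class II genes 10 of 13 rose (median 0.994, adjusted p = 0.000356, adjusted p = 0.0830 with an estimated correlation), with Cd74 at 5.04 ± 0.13. The pre-cDC gate took cells without surface MHC class II, which the CDP gate does not name, so these genes are no findings. Batf3 rose by 3.30 ± 0.15 and Zbtb46, a transcription factor gene of classical dendritic cells, by 2.39 ± 0.20. Of 9 cDC1 genes 5 rose (median 0.479, adjusted p = 0.0132, adjusted p = 0.124 with an estimated correlation). The cDC2 list (6 of 11, median 0.722, adjusted p = 0.0273, adjusted p = 0.165 with an estimated correlation) and the core list (7 of 14, median 0.340, adjusted p = 0.0132, adjusted p = 0.170 with an estimated correlation) passed as well. The cDC2 list holds Sirpa (CD172a) and the core list Itgax (CD11c). The pre-cDC gate took both markers and the CDP gate does not name them, so these members are no findings. The sizes of these list medians depended on the scaling, from array medians to the highest of the other scalings: 0.525 to 1.55 for class II, 0.0107 to 1.05 for cDC1, 0.253 to 1.28 for cDC2 and -0.129 to 0.982 for the core list. With no filter the cDC2 median was 0.225.

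Genes of other blood cells and of cell stress moved in the same step. Secondary granule and mature neutrophil genes were higher in pre-cDC than in CDP in 10 of 13 cases (median 4.86, and 3.58 at bounds, adjusted p = 4.45e-06, and 0.0282 with an estimated correlation): the alarmin gene S100a9 by 6.47 ± 0.07 (SE), S100a8 by at least 79.0-fold and Ltf by at least 12.5-fold. Basophil genes rose in 6 of 7 (median 1.81, adjusted p = 0.000194, and 0.0290 with an estimated correlation), led by the proteases Prss34 (3.07 ± 0.12) and Cpa3 (3.05 ± 0.16). Of 13 stress and dissociation genes 9 rose (median 3.74, and 3.25 at bounds, adjusted p = 0.000194, and 0.0290 with an estimated correlation), with Fos at 5.52 ± 0.06 and the RNA-binding protein gene Zfp36 at least 54.2-fold higher. T and NK genes rose in 4 of 5 (median 2.06, adjusted p = 0.0151, adjusted p = 0.108 with an estimated correlation). Primary granule genes fell in 8 of 12 (median -1.94, adjusted p = 0.280), with the myeloperoxidase gene Mpo at -3.45 ± 0.08. Ribosome biogenesis genes fell in 13 of 15 (median -1.69, adjusted p = 0.0132, adjusted p = 0.165 with an estimated correlation), Myc itself by 2.04 ± 0.13, and cell cycle genes in 19 of 25 without a call for the list (median -0.768, adjusted p = 0.147). The sizes of these medians depended on the treatment of dim probes. With normexp they were 1.5 for secondary granule, 0.65 for basophil and 2.12 for stress genes. With no filter on dim probes they were 2.16 for secondary granule, 1.09 for basophil and 0.287 for T and NK genes, and the cell cycle (adjusted p = 0.00238), stem (0.0454) and reference lists (0.0227) were called lower. With a stricter filter they were 1.67 for secondary granule and 1.80 for stress genes. The ribosome median was -1.12 with quantile normalization and -1.06 in the authors' table.

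Further lists were tested in this step, in which the median of all genes was -0.543. Transcription factor genes passed upward (17 rose and 12 fell of 34, median 0.317, adjusted p = 0.00612, adjusted p = 0.0846 with an estimated correlation). So did chemokine receptors (4 and 2 of 9, median 0.690, adjusted p = 0.0219, adjusted p = 0.108 with an estimated correlation) and monocyte genes (8 and 5 of 16, median 0.170, adjusted p = 0.0410, adjusted p = 0.232 with an estimated correlation). Toll-like receptors passed as well (7 and 5 of 15, median 0.222, adjusted p = 0.0410, adjusted p = 0.124 with an estimated correlation). The eosinophil list had a median of -0.0613 and a mean of -0.124 and was tested upward without a call (adjusted p = 0.242), as were the interferon (-0.274, 0.304) and cytokine receptor lists (-0.428, 0.615). Of 11465 genes 9650 passed, 28.4% of them higher, and 4884 changed at least 2-fold; 14 lists passed, 4 with an estimated correlation. The median of all genes moved to -0.315 with normexp, -0.233 with quantile normalization, -0.207 in the authors' table, -1.01 with array medians and 0.0140 with the percentile over probes detected on all arrays. The share of higher calls was then 28.9% (normexp), 38.4% (quantile), 39.5% (authors' table), 16.5% (array medians) and 51.1% (detected probes), and with no filter on dim probes 32.3%. With array medians the medians of 4 called lists crossed 0: core (-0.129), monocyte (-0.298), Toll-like receptor (-0.246) and transcription factor (-0.151). Upward, with the percentile over detected probes, the medians reached 0.726 (monocyte), 0.779 (Toll-like receptor), 0.874 (transcription factor) and 1.25 (chemokine receptor). The chemokine receptor median was 0.113 with normexp, 0.0150 with a stricter filter and 0.421 without CDP replicate 2, and the monocyte median 0.108 without CDP replicate 1. With no filter on dim probes the cDC2, monocyte and Toll-like receptor lists were not called (adjusted p = 0.132, 0.132 and 0.101), and with a stricter filter the chemokine receptor and T and NK lists (0.314 and 0.104). The Toll-like receptor list lost its call without CDP replicate 1 (0.0526) or pre-cDC replicate 1 (0.0557), and the monocyte list without CDP replicate 1 (0.0566). Scaling ended calls as well. The Toll-like receptor list lost its call with quantile normalization (0.0540) and in the authors' table (0.10), the monocyte list with array medians (0.0865), and the T and NK list in the authors' table (0.0570). With the percentile over detected probes these lists were not called (0.0942, 0.0792 and 0.0895), nor were the cDC2 (0.116) and chemokine receptor lists (0.0581). Irf8 differed by 0.11 ± 0.07 (SE, adjusted p = 0.176), with a change of -0.36 with array medians (adjusted p = 0.0243) and called rises of 0.39 (normexp) to 1.05 (quantile normalization) under the 4 other scalings. Each group again lay on its own slide.

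From WT pre-cDC to splenic WT CD8+ cDC, the cDC1 genes rose in 14 of 16 cases and fell in 2 (median 5.45, and 5.06 at bounds, adjusted p = 9.76e-05, adjusted p = 0.0623 with an estimated correlation). The profilin receptor gene Tlr11 was at least 222-fold, the chemokine receptor gene Xcr1 at least 69.1-fold and the scavenger receptor gene Cd36 at least 62.4-fold higher. Class II genes rose in 11 of 13 (median 3.15, adjusted p = 0.00240, adjusted p = 0.120 with an estimated correlation), including H2-Eb1 by 5.77 ± 0.11 (SE), H2-Aa by 5.44 ± 0.26 and their transactivator gene Ciita by 5.27 ± 0.46; surface MHC class II differed between the gates, so these genes are no findings. Among single genes outside the lists, Cd86 rose by 6.89 ± 0.22 and Cd83 by at least 686-fold. The core list rose in 11 of 14 (median 0.924, adjusted p = 0.0302, adjusted p = 0.221 with an estimated correlation) and the Toll-like receptor list in 13 of 18 (median 0.443, adjusted p = 0.0302, adjusted p = 0.120 with an estimated correlation).

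Lists of cell cycle and stem genes, and several of other blood cells, were lower in CD8+ cDC. Cell cycle genes fell in 24 of 25 cases (median -1.53, adjusted p = 4.39e-09, adjusted p = 0.159 with an estimated correlation), with the topoisomerase gene Top2a at -2.76 ± 0.10 (SE). Primary granule genes fell in 12 of 12 (median -2.94, and -2.73 at bounds, adjusted p = 1.19e-06, adjusted p = 0.0572 with an estimated correlation), with Mpo at -8.46 ± 0.08. Plasmacytoid genes fell in 9 of 14 (median -3.52, adjusted p = 0.000315, adjusted p = 0.0895 with an estimated correlation), with Cox6a2 at -8.57 ± 0.05 and Ly6d at -7.91 ± 0.26. Basophil genes fell in 6 of 7 (median -4.75, and -2.89 at bounds, adjusted p = 0.00141, adjusted p = 0.0623 with an estimated correlation). Stem and progenitor genes fell in 12 of 14 (median -2.34, adjusted p = 0.00141, adjusted p = 0.0623 with an estimated correlation) and monocyte genes in 13 of 18 (median -2.09, adjusted p = 0.0115, adjusted p = 0.159 with an estimated correlation), with Cx3cr1 at -4.74 ± 0.07. The cDC2 receptor genes Clec10a and Cd209a changed by -5.29 ± 0.11 and -5.08 ± 0.21. Hba-a1 was higher by 5.56 ± 0.06 in the splenic cells, at a level of 7.57. Irf8 fell by 0.46 ± 0.07 (SE, adjusted p = 0.000485), and by 0.20 without a call when arrays were scaled to their medians (adjusted p = 0.183). Of 12582 genes 9394 passed (54.0% higher, and 66.8% with array medians, which moved the median of all genes from 0.0842 to 0.341, but 37.3% with no filter on dim probes, where that median was -0.437), 4136 changed at least 2-fold, and 10 lists passed, none of them with an estimated correlation. The stress list had its median and mean on opposite sides of 0 (-0.277 and 0.20, adjusted p = 0.462). With a stricter filter on dim probes the basophil and Toll-like receptor lists were not called (adjusted p = 0.184 and 0.0977), and the latter was not called in the authors' table (0.108). With normexp the medians were smaller, at -1.62 (basophil), -1.84 (primary granule) and -1.15 (stem). With no filter they were -2.16 (basophil) and -1.23 (stem), and with a stricter filter -1.61, -1.08 and 0.261 (Toll-like receptor). The Toll-like receptor median was 0.70 with array medians. Of the lists not called, interferon genes passed upward without pre-cDC replicate 2 (0.0392), with no filter (0.00109) and with the percentile over detected probes (0.0493). Secondary granule genes passed downward with normexp (0.0185), quantile normalization (0.0393), array medians (0.00719), the authors' table (0.0396) and the 4 arrays alone (0.0213). With array medians the eosinophil (0.0179) and transcription factor lists (0.0234) passed downward. Slide, cell type and tissue cannot be told apart here.

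All 19 secondary granule and mature neutrophil genes were higher in Neu than in GMP (median 12.2, and 11.2 at bounds, adjusted p = 5.18e-07, adjusted p = 0.0697 with an estimated correlation): the cathelicidin gene Camp by 13.67 ± 0.19 (SE), Chil3 by 11.66 ± 0.30, and Ltf by at least 19080-fold. Cebpe rose by 3.25 ± 0.16. The primary granule list missed the threshold (10 fell and 3 rose of 13, median -3.97, adjusted p = 0.0602), although Elane fell by 5.84 ± 0.05 and the proteinase 3 gene Prtn3 by 7.93 ± 0.09. It passed with normexp (0.0238), with no filter (0.00355) or a stricter filter on dim probes (0.0241) and in the authors' table (0.0493). Interferon response genes rose in 12 of 15 (median 2.61, adjusted p = 0.00679, adjusted p = 0.112 with an estimated correlation), with the antiviral gene Rsad2 at 5.49 ± 0.26. Toll-like receptor genes rose in 13 of 17 (median 2.32, adjusted p = 0.00679, adjusted p = 0.0952 with an estimated correlation). Cytokine receptor genes rose in 16 of 20 (median 1.96, adjusted p = 0.00908, adjusted p = 0.242 with an estimated correlation), among them the IL-1 decoy receptor gene Il1r2 at least 440-fold. Jaml, an adhesion molecule gene of the core dendritic cell list, rose by 9.42 ± 0.09.

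Growth genes were lower in neutrophils. All 25 cell cycle genes fell (median -3.63, adjusted p = 2.57e-07, adjusted p = 0.204 with an estimated correlation), the replication helicase gene Mcm2 by 7.02 ± 0.09 (SE). All 16 ribosome biogenesis genes fell (median -5.83, and -5.56 at bounds, adjusted p = 1.48e-05, adjusted p = 0.0952 with an estimated correlation), with Myc at least 137-fold lower. Stem and progenitor genes fell in 14 of 16 (median -4.33, adjusted p = 0.00171, adjusted p = 0.0939 with an estimated correlation). Erythroid genes fell in 10 of 12 (median -5.13, adjusted p = 0.0156, adjusted p = 0.112 with an estimated correlation) and basophil genes in 10 of 12 (median -4.47, and -2.78 at bounds, adjusted p = 0.0352, adjusted p = 0.196 with an estimated correlation). Cd34, the stem cell sialomucin gene, changed by -8.25 ± 0.13 and Gata1 was at least 122-fold lower. Of 12506 genes 11552 passed (49.8% higher, 41.5% with array medians and 55.3% with a stricter filter on dim probes), and 8798 changed at least 2-fold. Of the lists 9 passed, none of them with an estimated correlation. The core and class II lists had medians of -0.171 and 0.473 with means of 0.161 and -0.178, and neither was called (adjusted p = 0.910 for both). The median of all genes, -0.00168, moved to -0.195 with quantile normalization, -0.475 with array medians and -0.301 with the percentile over detected probes. With a stricter filter on dim probes the basophil and erythroid lists were not called (adjusted p = 0.510 and 0.218), nor was the basophil list with normexp (0.0730) or the percentile over detected probes (0.0556). The basophil median was -1.58 with normexp and -1.40 with the stricter filter, which also gave 7.85 for the secondary granule list. The cDC1 list, not called here, passed with array medians (0.0482). Slide and cell type cannot be told apart here.

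The mature cells, CD8+ cDC and Neu, stand at opposite ends of the myeloid branches and shared a slide. All 16 cDC1 genes were higher in CD8+ cDC (median 7.61, and 6.20 at bounds, adjusted p = 2.38e-05, adjusted p = 0.0535 with an estimated correlation), with Batf3 at 8.80 ± 0.15 (SE), Irf8 at 8.59 ± 0.07 and Tlr11 at least 249-fold. All 13 class II genes were higher as well (median 6.50, adjusted p = 2.14e-05, adjusted p = 0.0535 with an estimated correlation), H2-Aa by 10.88 ± 0.26. Surface class II was part of the dendritic cell gate, so these genes are no findings. All 19 secondary granule genes (median -11.6, and -11.3 at bounds, adjusted p = 1.38e-07, and 0.0349 with an estimated correlation) and all 13 primary granule genes (median -5.14, and -4.00 at bounds, adjusted p = 2.38e-05, and 0.0349) were lower. They include the whey acidic protein domain gene Wfdc21 (-12.95 ± 0.10), Ltf (-12.71 ± 0.26) and Mpo (-5.91 ± 0.08). Cebpe fell by 11.69 ± 0.16 and Gfi1 was at least 99.2-fold lower. Cell cycle genes were higher in 24 of 25 cases (median 2.44, adjusted p = 5.12e-07, adjusted p = 0.253 with an estimated correlation). Ribosome biogenesis genes were higher in 16 of 16 (median 4.35, and 3.40 at bounds, adjusted p = 1.78e-05, adjusted p = 0.0787 with an estimated correlation), with the fibrillarin gene Fbl at 5.63 ± 0.08. The core list was higher in 12 of 14 (median 3.92, adjusted p = 0.00101, adjusted p = 0.165 with an estimated correlation), with the cytokine receptor gene Flt3 at 8.70 ± 0.17 and 1 of 2 Neu arrays well above background for it. Basophil genes fell in 5 of 5 (median -4.27, and -3.07 at bounds, adjusted p = 0.0145, adjusted p = 0.110 with an estimated correlation) and cytokine receptors in 14 of 19 (median -1.07, adjusted p = 0.0365, adjusted p = 0.394 with an estimated correlation). Of 12802 genes 10988 passed (51.1% higher, 58.3% with the percentile over detected probes, 43.8% with a stricter filter on dim probes and 38.5% with no filter), 7476 changed at least 2-fold, and 9 lists passed, 2 with an estimated correlation. Within the slide, the 4 arrays alone called 10884 genes and 8 lists, without the cytokine receptor list (adjusted p = 0.0503). That list was not called with normexp (0.0659) or with no filter (0.0701) either. A stricter filter on dim probes ended the calls of the cytokine receptor (0.0934) and basophil lists (0.156). With normexp the medians were smaller, at 4.70 (cDC1), -2.40 (primary granule), -1.76 (basophil) and 2.24 (ribosome biogenesis). With a stricter filter they were 4.97 (cDC1) and -2.74 (primary granule), and with no filter -1.36 (basophil). The stress list, not called here, passed with normexp (0.0193), with no filter (0.00427) and in the authors' table (0.0391). Medians and means lay on opposite sides of 0 for the plasmacytoid (-0.507 and 0.135), Toll-like receptor (-1.11 and 0.273) and reference lists (-0.316 and 0.00305), none of them called. The median of all genes, -0.00231, moved to 0.143 with quantile normalization, 0.232 with array medians and 0.280 with the percentile over detected probes.

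**Figure D3:**
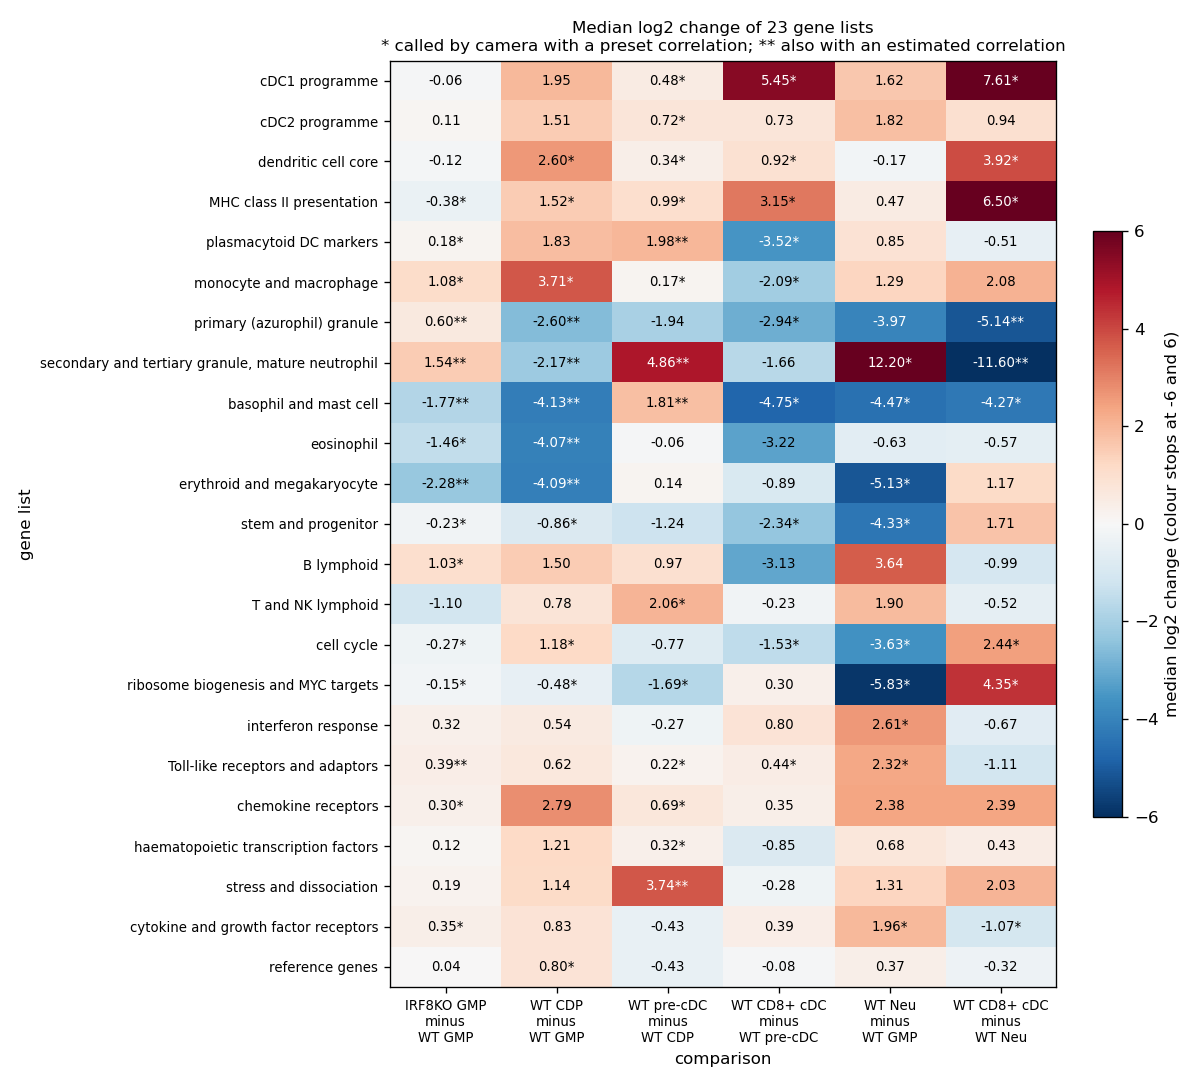
Median log2 change of the measured members of 23 gene lists (vertical) in 6 comparisons (horizontal); colour gives the median and stars mark the lists called by camera with a preset and also with an estimated correlation. Erythroid and basophil medians are below 0 in the arrays labelled IRF8KO GMP (-2.28 and -1.77) and in CDP (-4.09 and -4.13), each against WT GMP.

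Genes that differed with the label IRF8KO in progenitors were then read in the mature cells, to ask whether they separate dendritic cells from neutrophils. Those at least 2-fold higher in the arrays labelled IRF8KO GMP were lower in CD8+ cDC than in Neu: of 239 measured, 161 were lower and 64 higher (median -2.26, camera's adjusted p = 7.17e-06 over 10 set tests, and 0.0123 with an estimated correlation). Within the slide the median was -2.21, and with no filter on dim probes it was -1.15. Mmp8 and Cd177 were in this group, at least 11780-fold and 1427-fold lower in CD8+ cDC, and so was Ednra, an endothelin receptor gene, at least 19.9-fold higher in the arrays labelled IRF8KO and at least 61.6-fold lower in CD8+ cDC. Against the group, Flt3 was 2.84-fold higher in the arrays labelled IRF8KO (not called with the mean of its probes, log2 change 1.28 and adjusted p = 0.121, or with its median-change probe, 1.05 and 0.587) and the log2 change of Sult1a1, a sulfotransferase gene, was 1.75; both were higher in CD8+ cDC (8.70 and 7.22 on the log2 scale). The genes at least 2-fold lower in the arrays labelled IRF8KO were not called as a set: of 207 measured, 106 were higher and 87 lower in CD8+ cDC (median 0.628, adjusted p = 0.791). This set was built anew under each alternative, so the medians there are of sets with other members. They took the other sign with normexp (-0.236), no filter (-0.753) and a stricter filter on dim probes (-0.692), and without WT GMP replicate 2 (-0.135). Leaving out a WT GMP array alters the members alone, since the changes between the mature cells stay as they were. Ly86 (higher in CD8+ cDC by 7.25) and Aif1, an actin-binding protein gene of macrophages (7.70), went with the dendritic cells; Myo1d, an unconventional myosin gene (at least 395-fold lower), went with the neutrophils. Overlaps of at least 2-fold calls among 11463 genes were 150 for higher and then lower (60.9 if independent), 99 for lower and then higher (66.5), 74 for lower in both (52.7) and 63 for higher in both (76.7). The across-gene correlation was r = -0.195 (rho = -0.226); genes are not independent replicates.

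**Figure D4:**
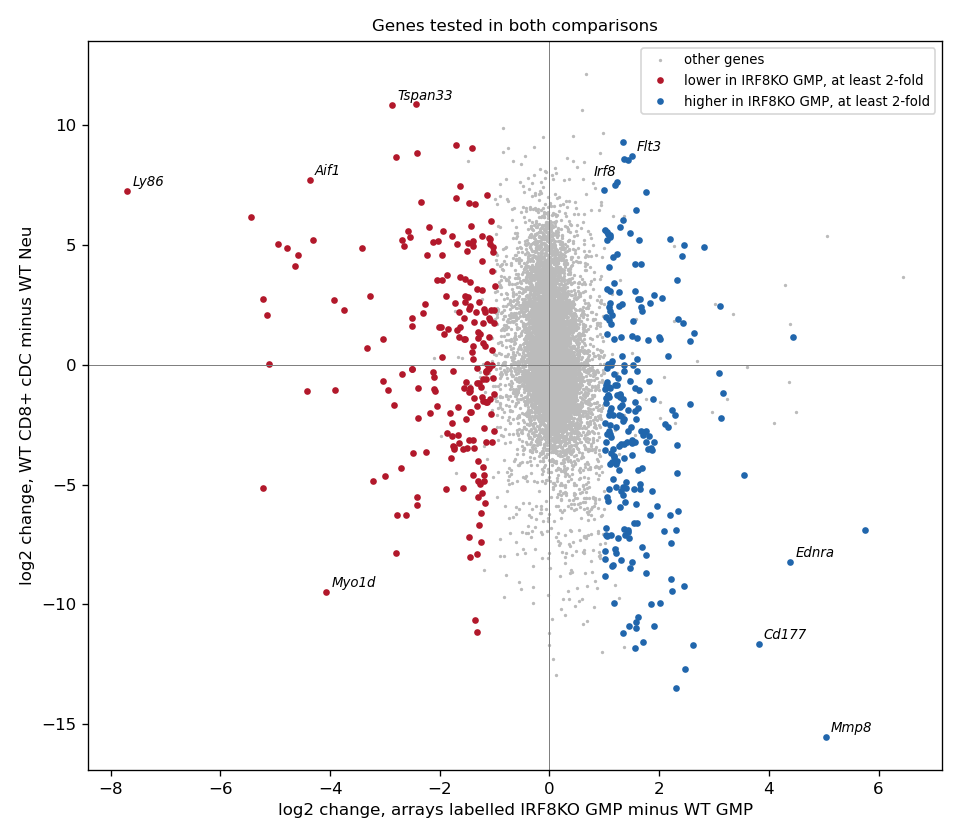
Log2 change of 11463 genes, arrays labelled IRF8KO GMP minus WT GMP (horizontal) against CD8+ cDC minus Neu (vertical), each point a gene; red and blue mark the 207 and 239 genes at least 2-fold lower and higher in the arrays labelled IRF8KO. Most blue points, 161, lie lower in CD8+ cDC, and the red points fall on both sides.

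The same sets were read in the other comparisons, of which CDP and Neu against GMP share the WT GMP arrays. Genes lower in the arrays labelled IRF8KO were mostly lower in CDP, 245 of 328 against 55 higher (median -2.13, adjusted p = 7.43e-22, and 0.00503 with an estimated correlation). In Neu 239 were lower and 71 higher (median -2.60, adjusted p = 3.30e-05, and 0.0402 with an estimated correlation). Genes higher in the arrays labelled IRF8KO were mostly higher in Neu than in GMP, 159 of 243 against 72 (median 2.10, adjusted p = 4.08e-05, and 0.0240 with an estimated correlation). In CDP 124 of 232 were higher and 81 lower (adjusted p = 0.468). The lower set passes the filter through WT GMP, so the sets were also set against genes of the same filter and WT GMP level. Over 100 draws of such genes the medians were -0.0231 to 0.245 for the lower set in CDP, -0.603 to 0.344 for it in Neu, and 0.112 to 0.928 for the higher set in Neu. Against genes of the same filter the adjusted p was 2.99e-21, 0.000297 and 5.13e-06, and with an estimated correlation 0.00229, 0.0588 and 0.00911, so the lower set in Neu was then not called. From CDP to pre-cDC both sets passed upward relative to the other genes, the lower set with a median of 0.150 (adjusted p = 5.60e-06, and 0.0292 with an estimated correlation) and the higher set with 0.0236 (0.000257, and 0.0282). From pre-cDC to CD8+ cDC neither was called (adjusted p = 0.810 and 0.0717). Across genes the changes correlated at r = 0.289 with those of CDP and 0.267 with those of Neu. Unchanged groups simulated against these controls gave r = 0.50 in both, with a covariance of 0.0190 against the observed 0.211 (CDP) and 0.398 (Neu). Part of the shared direction may therefore come from the shared arrays. With the simulated covariance taken off, 0.192 (CDP) and 0.379 (Neu) remained. The simulated groups hold no changes, so the size of their r cannot be set against the observed r.

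The CD4+ cDC arrays, of a smaller design on a slide of their own, give values with no test. All 16 cDC1 genes read lower in CD4+ than in CD8+ cDC (median -5.65), and 15 of 16 in the authors' table (median -4.28), where Batf3 was higher by 0.25. Clec9a read -0.72 ± 0.35 (SD, n = 2) against 6.54 ± 0.06, Naaa, an amidase gene, 2.08 ± 0.17 against 8.25 ± 0.04, and Irf8 2.32 ± 0.25 against 8.62 ± 0.13. These values are relative to percentiles over the differing probes of each design. With the percentile over the probes that both designs share, the cDC1 median was -4.55. The CD8+ cDC arrays then read 7.53 for Irf8, 5.44 for Clec9a and 7.15 for Naaa. Batf3 differed by -0.301 instead of -1.40. Cd8a, on this list, encodes a gate marker and is no finding. Of 14 cDC2 genes 10 read higher in CD4+ cDC (median 1.72), 9 with normexp and 11 in the authors' table (median 3.17). With the shared-probe percentile the median was 2.82. The lectin receptor gene Clec4a4 read 4.32 ± 0.04 against -1.78 ± 0.12, the Notch pathway gene Dtx1 5.60 ± 0.13 against -0.89 ± 0.05 and Sirpa, the CD172a gene, 4.88 ± 0.07 against 0.61 ± 0.05. Against these, Notch2 and Rbpj, also of the Notch pathway, differed by -1.65 and -1.58 (-0.558 and -0.487 with the shared-probe percentile). Mgl2 and Cd209e read lower in CD4+ cDC as well (-1.56 and -3.75). Cd4, on this list, encodes a gate marker and is no finding. As a check of the labels it separated the groups little, at 3.35 ± 0.32 in CD4+ and 3.05 ± 0.20 in CD8+ cDC. The difference was 0.302, and it was -0.280 with normexp, 1.40 with the shared-probe percentile and 1.64 in the authors' table. The cause was not tested. For 13 class II genes the median was -0.967, and with the percentile taken over the probes that both designs share it was 0.128 and 0.814 with the authors' values.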

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

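All 10 tests of explanations in this part were chosen after the results were seen. Probes to which no gene symbol could be given, which no comparison above uses, also differed between the arrays labelled IRF8KO GMP and WT GMP: 309 of 9502 tested changed at least 2-fold (180 higher and 129 lower, 3.25%), and 1041 passed in all.

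Erythroid, basophil and eosinophil genes were lower in the arrays labelled IRF8KO GMP, with a median of -1.79 over 30 measured members. Scaling is argued against, since the median stayed between -1.94 and -1.71 over 5 other scalings and backgrounds. A lower share of every cell type other than the progenitor would also lower secondary granule and B lymphoid genes. Their median lay 3.32 above that of these members. Both lists had already been seen to rise, so this restates that not all such lists fell and is no separate test. The standard error of 0.474 is taken across list members, which are not independent replicates, and not from the fit. With no filter on dim probes the B lymphoid median was 0.0679. T and NK genes, left out here, had a median of -1.10 (camera adjusted p = 0.293). A candidate explanation that stays open is fewer erythroid, basophil and eosinophil precursors inside the sorted gate. That 90% of the members (27 of 30) were called lower is the pattern itself and does not test it. Arrays of pooled cells cannot part fewer such cells from less RNA in each of them.

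The Irf8 probe was brighter in the arrays labelled IRF8KO GMP than in WT GMP, by 1.36. Scaling is argued against, as the change stayed between 1.27 and 1.43 over 5 other scalings and backgrounds and was called in each. An exchange of labels between the GMP groups stays open: Ly86, at 7.12 in WT CDP, was held by the arrays labelled WT GMP and not by those labelled IRF8KO, which speaks against an exchange only if Ly86 needs IRF8. A candidate explanation is transcript of a disrupted gene outside its deleted part, and with 1 probe of unknown position in the gene it could not be tested.

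Secondary granule and mature neutrophil genes were brighter in pre-cDC than in CDP, by a median of 4.86. Scaling is argued against, since the median stayed at 4.40 or more over 4 other scalings. Background as the whole cause is argued against too: with normexp correction the list kept its call (camera's adjusted p = 1.08e-06). Its median was then 1.5. That setting also adds a fixed offset to every spot, which by itself shrinks the changes of dim genes. How much of the smaller median comes from the background therefore cannot be told. RNA of neutrophils like those measured, at one share, is argued against as the whole cause for a few members, and not for the list. Pre-cDC minus Neu spread over at least 6.75 on the log2 scale among 12 members that read at least 8 in Neu and below 0 in CDP. Of these, 7 lay between -9.93 and -8.37, as near to each other as one share needs, with S100a8 at -7.45 and S100a9 at -5.63 above them. The other 3 were not well above background in pre-cDC. Even at the lowest of these shares they should have been brighter, Mmp8 by 2.45, Fpr1 by 0.963 and Itgb2l by 0.954 than their bounds, and 98.5% of genes at the levels needed were well above background. The spread rests on S100a8, S100a9 and Mmp8, and Mmp8 read brighter in CDP (-0.610) than in pre-cDC (-2.66). Without them the members ran from -8.37 to -10.89 (Fpr1 at its bound), a range too narrow to argue against one share. The slide cannot be told apart from the group, because the slide of the pre-cDC arrays held 1 group. Neutrophil precursors among the sorted cells may be the source and were not tested; the gate for CD11c and CD135 would remove cells without those markers.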

How the results depend on the processing

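The percentile over probes well above background on all 12 arrays was chosen after the data were seen; the other alternatives were listed before. Irf8 stayed higher in the arrays labelled IRF8KO GMP, and called, under all 16 alternatives. Counts of called genes stayed within 1.5 times the value given in 98 of 108 cases, and counts of lists in 77 of 84. Among genes named in the text, 2020 of 2029 values kept direction and side of the threshold. These genes were named mostly for their large changes in these data, so this share says little about other genes. For single lists 1784 of 1927 values were counted as the same, with 94 calls lost (most with an estimated correlation) and 47 gained. A list counted as the same could still have a median that changed sign. From CDP to pre-cDC with array medians, the core, Toll-like receptor and transcription factor medians became negative (-0.129, -0.246 and -0.151), and these lists stayed called.

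Genes called between the arrays labelled IRF8KO GMP and WT GMP, 3050, fell to 1484 with array medians, 628 at 2-fold or more, 1684 at an adjusted p under 0.01, and 1662 to 1869 with 1 array left out, where fewer arrays give less power and the lone array is assumed to vary like the other groups. The 2-fold minimum gave 4120 (CDP and GMP), 4884 (pre-cDC and CDP) and 4136 (CD8+ cDC and pre-cDC) genes. With an estimated correlation camera called 5 lists for IRF8KO GMP, 5 for CDP, 4 for pre-cDC, 0 for CD8+ cDC against pre-cDC, 0 for Neu against GMP and 2 for CD8+ cDC against Neu, and the added percentile called 9 for pre-cDC. Irf8 turned to -0.36 from CDP to pre-cDC with array medians. The reference genes turned to -0.27 (quantile) and -0.23 (authors' table) from GMP to CDP. The cause of these changes, the lists lost with an estimated correlation included, was not tested. For CD4+ against CD8+ cDC the median was -4.86 with normexp and -4.55 with the shared-probe percentile for cDC1 genes, 1.42 and 2.82 for cDC2 genes and -0.559 and 0.128 for class II genes.

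Replicate numbers did not pair the arrays: over 15 pairs of groups, the correlation of same-numbered arrays' deviations was -0.0614 to 0.0387. With the replicate block, 2678, 9171, 9574, 9282, 11496 and 10908 genes were called in the 6 comparisons in the order given. Leaving out saturated spots was not run, as no spot was saturated. Dim genes are limited by the signal over background: the median spot signal and local background were 74 and 51, and 77 and 52, on the pre-cDC arrays, and 44 and 21, and 41 and 21, on the CDP arrays, whose processed signal was lowest.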

Other observations

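Several lists that missed the threshold held genes with large changes. Of 7 chemokine receptor genes 5 rose and 2 fell from GMP to CDP (median 2.79, and 2.47 at bounds, camera adjusted p = 0.303): Cxcr3, a receptor gene of the interferon-induced chemokines, was at least 5.53-fold higher and the neutrophil receptor gene Cxcr2 at least 6.34-fold lower. The list passed with normexp (0.0325) and with the percentile over detected probes (0.0477). Of 16 Toll-like receptor genes 9 rose and 4 fell (median 0.618, adjusted p = 0.718), with Tlr12 higher by 3.24 ± 0.38 (SE) and the endotoxin receptor gene Tlr4 at least 4.25-fold lower. All 3 B lymphoid genes rose in CDP (median 1.5, adjusted p = 0.142), with the adaptor gene Blnk at 5.46 ± 0.22, and the list passed with normexp (0.0491) and the percentile over detected probes (0.0349). Interferon response genes read lower in CD8+ cDC than in Neu in 9 of 15 cases (median -0.665, adjusted p = 0.0975), with Oasl2 at -6.40 ± 0.08 and Ifit3 at -4.95 ± 0.24.

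Lymphoid and erythroid genes were measured in cells whose gates did not select for them. In Neu, 6 of 7 B lymphoid genes were higher than in GMP (median 3.64, and 2.46 at bounds, camera adjusted p = 0.204). Cd3d, a T cell receptor chain gene, was at least 164-fold higher. Of 7 T and NK genes 4 were higher and 3 lower, and that list was not called (median 1.90, camera adjusted p = 0.66). In splenic CD8+ cDC the heme synthesis gene Alas2 was at least 30.8-fold higher than in pre-cDC, beside the alpha globin gene given above, while 8 of 12 erythroid genes were lower and 2 higher (median -0.892, adjusted p = 0.102). The B cell gene Ms4a1 was at least 33.1-fold higher in CD8+ cDC than in pre-cDC, and the B lymphoid list was not called (median -3.13, adjusted p = 0.20). With array medians the erythroid and B lymphoid lists were called lower (0.0449 for both).

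In the authors' table, 432 probes stand for several spots each on the larger design and 399 on the smaller. Their rank correlation with the array's own scanner value was 0.964 to 0.998 on 10 arrays of the larger design, 0.996 and 0.997 on the CD4+ cDC arrays, and 0.339 and 0.324 on the pre-cDC arrays. There it was 0.780 and 0.772 with the mean of the probe and the next 9 such probes in name order, a window chosen after many others had been tried; on the 10 other arrays of the larger design that value was 0.211 to 0.330.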
